A study of Mus musculus with 2 samples.

How the data were processed

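Sections of C10 tumors from mice without Rag1 were profiled with a CytAssist spatial kit for fixed tissue, in 2 capture areas. Both carried the same label, with PBS and Smarta together, so they formed 1 group. Spots are small areas that can hold several cells. Replicate 1 was used for spot positions alone and its expression was not analysed here. Replicate 2 was used for expression.

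The deposited matrix of replicate 2 holds raw UMI counts per gene and spot, with no normalization by the authors, for 19465 genes and 3480 spots under tissue. The submitters' processing notes name Space Ranger 2.0.1, bcl2fastq 2.20.0, STAR 2.7.2a and the mm10 build, with no role for each tool. The probe set version and the image alignment are not given in the sources used here. The deposited position tables, of unit other than counts, gave the lattice row and column of each spot. Probes read a short part of each transcript, so near-identical family members (granzymes, guanylate-binding proteins, MHC genes, keratins and receptor segments) may share signal and their single values are uncertain. Gene coordinates were taken by Ensembl identifier from GENCODE M21, which uses the mm10 build, for all 275 named features.

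Tissue pieces were groups of spots joined within 2 lattice steps, with at least 100 spots, numbered by mean array column. The labels gave 2 sections per condition and did not say which pieces came from the same tumor. The analysis plan expected 2 pieces and each area held 3. The planned pair, the 2 largest pieces, is pieces 1 and 3, and the pairs of piece 2 with piece 1 and with piece 3 were added after this was seen. Of 3480 spots, 3475 lay in a piece. Spots under 500 UMIs (5 spots, most of them outside the pieces) were left out too, which left 3474. Counts were summed per piece and divided by the piece's UMI total (CPM). With 1 library, no test was run and no p-value is given. Levels have exact Poisson intervals and ratios exact conditional binomial intervals at 95%, which cover counting error only, neither differences between sections nor the shift that a few strongly different genes give to all others on the CPM scale. Between pieces, genes needed 10 CPM in 1 piece and 100 UMIs over both, and counts of genes use a ratio of at least 2, as a rule of size. List members needed 20 UMIs and counted as different at 1.5-fold. The floor for a count of 0 was 3 counts.

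The 34 gene lists, the settings and the rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest ratios per pair, the 4 members of each list with the most UMIs, the 10 highest and 10 lowest mean log2 ratios of edge to interior among genes with 1 direction in every piece, and the 5 leading genes of each region, of which 1 is not reported here. It was applied to whole pieces and to interior spots, and the text gives part of the genes it took. The receptor segments were named after their values were seen. Of the listed genes, 20 had no feature. Edge spots lay at most 2 steps from outside the tissue and interior spots over 5 steps. Regions came from Leiden clustering (2000 variable genes, 30 components, 15 neighbours, resolution 0.5, seed 1) and are named by leading genes with at least 10 CPM. No cell-type deconvolution was run. For shares of spots, each spot was thinned to the 10th percentile of UMIs. Because bins at 3 or more steps from a marked spot held few spots before thinning, marked spots were also compared with all other spots, a comparison added later.

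Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used, with edgeR 4.0.16 for the TMM factor alone. The ratio step was tested on counts simulated with 200 changed genes per pair and Poisson error alone, the error that the intervals assume. Spread of real spots beyond counting error was left out. For pieces 2 and 1 (9403 genes), 67 of 67 genes changed 3-fold and 66 of 66 changed 4-fold passed the 2-fold rule, 0 of 67 changed 1.5-fold did, and 0 of 9186 unchanged genes did. The 95% intervals held the simulated ratio of 95.5% of those unchanged genes once the shift of the CPM scale by the changed genes was taken into account. With Poisson counts, coverage near 95% follows by construction. For genes changed 1.5-fold, 3-fold and 4-fold in this pair it was 91.0%, 92.5% and 95.45%. Alternatives covered the joining of spots, the UMI minimum, the scaling, the weight of spots, list members, interior spots, edge width, clustering settings and the marking and thinning of spots. Spots of 50000 to 100000 UMIs, the quadrants, the edge ratios without the most abundant list member and the pairs with piece 2 were added after the data were seen.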

Results

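Spatial gene expression was measured by probe hybridisation in sections of formalin-fixed, paraffin-embedded tumors grown from the C10 cell line in mice without Rag1, which lack mature T and B cells. Mice were given PBS or Smarta cells on day 4 and tumors were dissected on day 10. Smarta cells are T cell receptor transgenic CD4 T cells specific for a peptide of the lymphocytic choriomeningitis virus glycoprotein, and each of the 2 capture areas was labelled as carrying both PBS-treated and Smarta-treated tissue. The labels gave no map from spots or tissue pieces to a treatment, so no piece was assigned one and every comparison below is between places on the tissue, not between treatments. Replicate 1 had 7088 spots under tissue in 3 separate pieces of 3085, 1604 and 2399 spots, and its expression was not analysed here. Replicate 2 had 3480 spots under tissue, of which 3474 were kept, and its 3 pieces had 1156, 1089 and 1229 kept spots. The UMI total of replicate 2 was 274713692, with a median of 92940.5 per spot and a range of 17 to 178769. Pieces 1, 2 and 3 held 86073860, 103235224 and 85401949 UMIs, so that a count of 0 allowed a level of up to 0.0349, 0.0291 and 0.0351 CPM. With 1 library there was no replicate spread and no test. All intervals are 95% intervals of counting error only, and the range over the 4 quadrants of a piece describes unevenness within it, not replication.

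**Figure D1:**
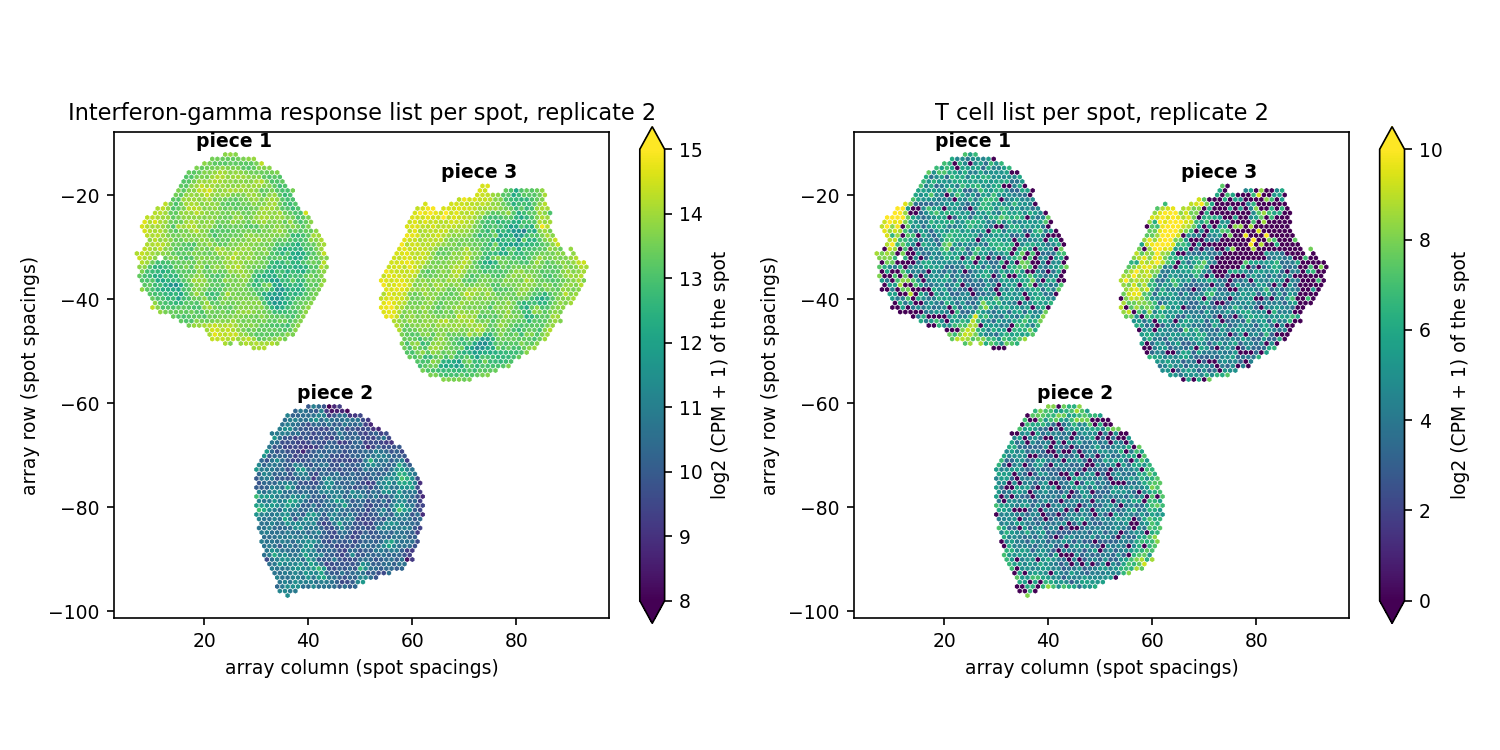
Spots of replicate 2 at their array positions (axes in spot spacings), colored by log2 (CPM + 1) of the interferon-gamma response list on the left and of the T cell list on the right, with colors capped at the ends of each scale. The interferon-gamma response list summed to 11927, 1620.4 and 11748 CPM in pieces 1, 2 and 3, and spots with the most T cell list transcripts lay at or near parts of the borders of pieces 1 and 3.

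Pieces 1 and 3, the 2 largest, differed most in muscle genes, which were lower in piece 1. The 12 genes with the lowest ratio of piece 1 to piece 3 were all genes of striated muscle, led by the skeletal alpha-actin gene Acta1 (0.790 against 277.57 CPM), the calcium pump gene Atp2a1 (0.290 against 94.2 CPM), Casq1, Myh4, Pvalb, Tnnc2, Tnnt3, Myl1, Ckm, Ttn, Tnni2 and Mybpc2. All 10 members of the skeletal muscle list were lower in piece 1, which had 16.0 CPM of the list against 961 CPM in piece 3. Muscle transcript lay in part of piece 3, whose quadrants ranged from 16.9 to 5335 CPM, and in interior spots the list had 15.2 and 28.9 CPM in pieces 1 and 3. On the other side, piece 1 had more Igfbp5 (24.6 against 7.29 CPM), Agt (20.4 against 6.28 CPM), Gzmc (302.6 against 96.2 CPM), Prf1 (53.3 against 23.5 CPM), Xcl1 (20.1 against 9.20 CPM), Gzmb (180.9 against 87.9 CPM), Gzmg, Klre1, Rgs1, Sertad4, Hspa1a and Hspa1b. Gzmb, Gzmc and Gzmg encode granzymes and Prf1 encodes perforin, the effector proteins of cytotoxic granules. The CD8 T and NK cell list was higher in piece 1, with a log2 ratio of 0.92 (95% interval 0.89 to 0.94) and 7 of 13 members at least 1.5-fold higher and 1 lower, although its quadrant ranges overlapped (238 to 488 CPM in piece 1 and 79.5 to 349.9 CPM in piece 3). Gzmb made up 48.8% of the list in piece 1 and 44.8% in piece 3, and without it the list had 190 and 109 CPM. The list holds genes of CD8 T cells and of NK cells together, so it does not tell which cells carried these transcripts.

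Of 9530 genes compared between pieces 1 and 3, 9 were at least 2-fold higher in piece 1 and 55 were at least 2-fold lower. The T cell list gave a log2 ratio of -0.23 (95% interval -0.29 to -0.17), which turned to 0.11 in interior spots, so no direction was read from it. Its quadrants in piece 3 ranged from 23.3 to 221 CPM. The interferon-gamma response list differed little, with a log2 ratio of 0.02 (95% interval 0.02 to 0.03) and 0 of 22 members at least 1.5-fold apart.

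Piece 2 had far less transcript of interferon-gamma response genes than either other piece. The list summed to 11927, 1620.4 and 11748 CPM in pieces 1, 2 and 3, a log2 ratio of -2.88 (95% interval -2.89 to -2.87) to piece 1 and -2.86 (95% interval -2.87 to -2.85) to piece 3. All 22 measured members were at least 1.5-fold lower in piece 2 in both pairs, and the quadrants of piece 2 (1442 to 1976 CPM) lay below every quadrant of piece 1 (10316 to 13417 CPM) and piece 3 (9946 to 16062 CPM). The pairs with piece 2 were added after the data showed 3 pieces. Both pairs share piece 2, and whether pieces 1 and 3 came from different tumors is not given, so the pairs are not independent comparisons. Gbp2, a guanylate-binding protein gene induced by interferon, had 2189, 147 and 1723 CPM in pieces 1, 2 and 3. The T cell attracting chemokine gene Cxcl9 (chromosome 5, 92321347 to 92328079 in mm10) had 472, 13.1 and 694 CPM. The inducible nitric oxide synthase gene Nos2 (chromosome 11, 78920787 to 78960254) had 164, 3.86 and 195 CPM. Ido1, Gbp4, Gbp8, Acod1 and Gm4841 were likewise among the genes with the lowest ratio of piece 2 to piece 1. Ifng itself (chromosome 10, 118441046 to 118445892), which encodes the cytokine, had 17.6, 0.552 and 18.5 CPM. Arg1, which encodes arginase 1, had 621, 27.7 and 611 CPM, and Cxcl3, Ccl24 and Car9 completed the 12 lowest.

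Several other immune lists were also lower in piece 2 as a whole. The type I interferon response list had 5923, 2742 and 6579.6 CPM in pieces 1, 2 and 3, with 12 of 13 members lower than in piece 1 and 13 of 13 lower than in piece 3. MHC class I presentation had 14958, 6711 and 13806 CPM, with 13 of 15 members lower in each pair, and B2m, the light chain gene of MHC class I, had 5381, 2519 and 4858 CPM. MHC class II presentation had 2273, 1015 and 2071 CPM, with 9 and 7 of 9 members lower. The T cell list had 49.1, 23.5 and 57.6 CPM, with 11 and 12 of 15 members lower, but among spots of 50000 to 100000 UMIs its log2 ratio to piece 3 was only -0.59, against -1.29 over all spots. The receptor constant-chain gene Trbc2 had 7.47, 2.58 and 15.3 CPM, Trbc1 9.77, 3.40 and 6.35 CPM and the kinase gene Lck 7.53, 2.87 and 5.83 CPM. The CD8 T and NK cell list had 371, 72.5 and 197 CPM, with 9 of 13 members lower and 1 higher than in piece 1 and 5 of 13 lower than in piece 3, and Gzmb had 181, 23.2 and 87.9 CPM. The Th1 effector list had 339, 184 and 383 CPM, with 6 and 5 of 11 members lower, and most of it was the chemokine gene Ccl5 at 291, 169 and 334 CPM. Transcripts of the monocyte list (833, 372 and 918 CPM), the neutrophil list (201, 80.5 and 181 CPM) and the inflammatory chemokine list (1846, 914 and 1891 CPM) were lower as well, and 10 of 12 chemokine members were lower in both pairs. At the edge, however, the neutrophil list was highest in piece 2, with 407, 578 and 287 CPM in pieces 1, 2 and 3, and its quadrants in piece 2 (36.5 to 209 CPM) overlapped those of piece 1 (110.4 to 305 CPM). For the T cell, Th1 effector, MHC class II and neutrophil lists some quadrants of piece 3 were as low as some of piece 2, whereas those of MHC class I and type I interferon genes were not.

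Hypoxia and sterol genes differed in opposite directions. All 12 measured members of the hypoxia list were lower in piece 2 in both pairs, and the list had 1917, 589 and 1630.5 CPM in pieces 1, 2 and 3, with the glucose transporter gene Slc2a1 at 338, 81.4 and 293 CPM. Glycolysis had 6423, 4029.7 and 5631 CPM. The cholesterol synthesis list was higher in piece 2 (988, 1695 and 775 CPM), with 9 of 12 members at least 1.5-fold higher than in piece 1 and 12 of 12 higher than in piece 3. Cyp51, a sterol demethylase gene, had 200.2, 368 and 153 CPM and Sqle, the squalene epoxidase gene, had 113, 218 and 88.4 CPM. Cell cycle genes had 2698, 3392 and 2661 CPM and oxidative phosphorylation genes 3955, 4734 and 3967 CPM.

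Epidermal genes were present in piece 2 and at low levels in the others. Krt14 had 1.94, 386 and 1.74 CPM, Krt5 0.523, 105 and 0.422 CPM and Krt10 8.28, 118 and 7.74 CPM in pieces 1, 2 and 3, and the highest ratios of piece 2 to piece 1 belonged to Krt15, Col17a1, Krt5, Krt14, Krt6a, Krt17, Krtdap, Krt6b, Crabp1, Krt1, Calm4 and Gjb2. The keratinocyte list had 21.1, 908 and 21.4 CPM, and in interior spots 19.8, 24.7 and 19.2 CPM. Among interior spots, the highest ratios of piece 2 to piece 1 were instead those of the fractalkine receptor gene Cx3cr1 (19.6 against 3.88 CPM), Mest (40.1 against 9.49 CPM), Stra6 (31.3 against 7.74 CPM) and Myl7. Over all spots, 108 genes were at least 2-fold higher and 405 at least 2-fold lower in piece 2 than in piece 1 of 9639 compared, and 127 were higher and 467 lower than in piece 3 of 9688. In interior spots only 23 and 56 genes were at least 2-fold higher, while 423 and 497 were lower.

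The remaining lists are given as levels. In pieces 1, 2 and 3 the fibroblast list had 4489, 3442 and 5521 CPM, the macrophage list 1498, 1121 and 1452 CPM, the dendritic cell list 841, 1102 and 869 CPM and the alternatively activated myeloid list 4408, 2515 and 3201 CPM. Fscn1 made up 93.0%, 96.0% and 93.4% of the dendritic cell list and Spp1 76.5%, 86.3% and 68.4% of the alternatively activated one. Without these genes the lists had 58.8, 43.8 and 57.7 CPM and 1035, 344 and 1012 CPM, so that the dendritic cell list was then lowest in piece 2. The endothelial list had 381, 432 and 463 CPM, the pericyte and smooth muscle list 127, 148 and 132 CPM and the TGF-beta and mesenchymal list 6219.9, 5361 and 5401 CPM. The cell death list had 1611, 1039 and 1546 CPM, the immediate early and heat shock list 1466, 1022 and 1312 CPM and the unfolded protein and integrated stress response list 2984, 2655 and 3366 CPM. At low levels, the T regulatory and checkpoint list had 79.4, 58.1 and 72.6 CPM, the adipocyte list 93.5, 157 and 103 CPM, the simple epithelial list 39.6, 40.1 and 29.4 CPM, the melanocytic list 30.1, 20.97 and 27.1 CPM, the Schwann cell and nerve list 25.4, 22.1 and 21.2 CPM and the mast cell and eosinophil list 16.7, 26.2 and 17.4 CPM. The adipocyte list and the mast cell and eosinophil list were higher in piece 2 over all spots and lower in interior spots. Fabp4 took 74.4%, 56.8% and 71.0% of the adipocyte list, Vim 66.0%, 70.5% and 66.0% of the TGF-beta and mesenchymal list and Mitf 65.3%, 50.9% and 67.2% of the melanocytic list. The B cell list, whose cells these mice lack and of which Pax5 made up 49.9%, 58.1% and 60.2%, had 31.6, 37.3 and 34.7 CPM.

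**Figure D2:**
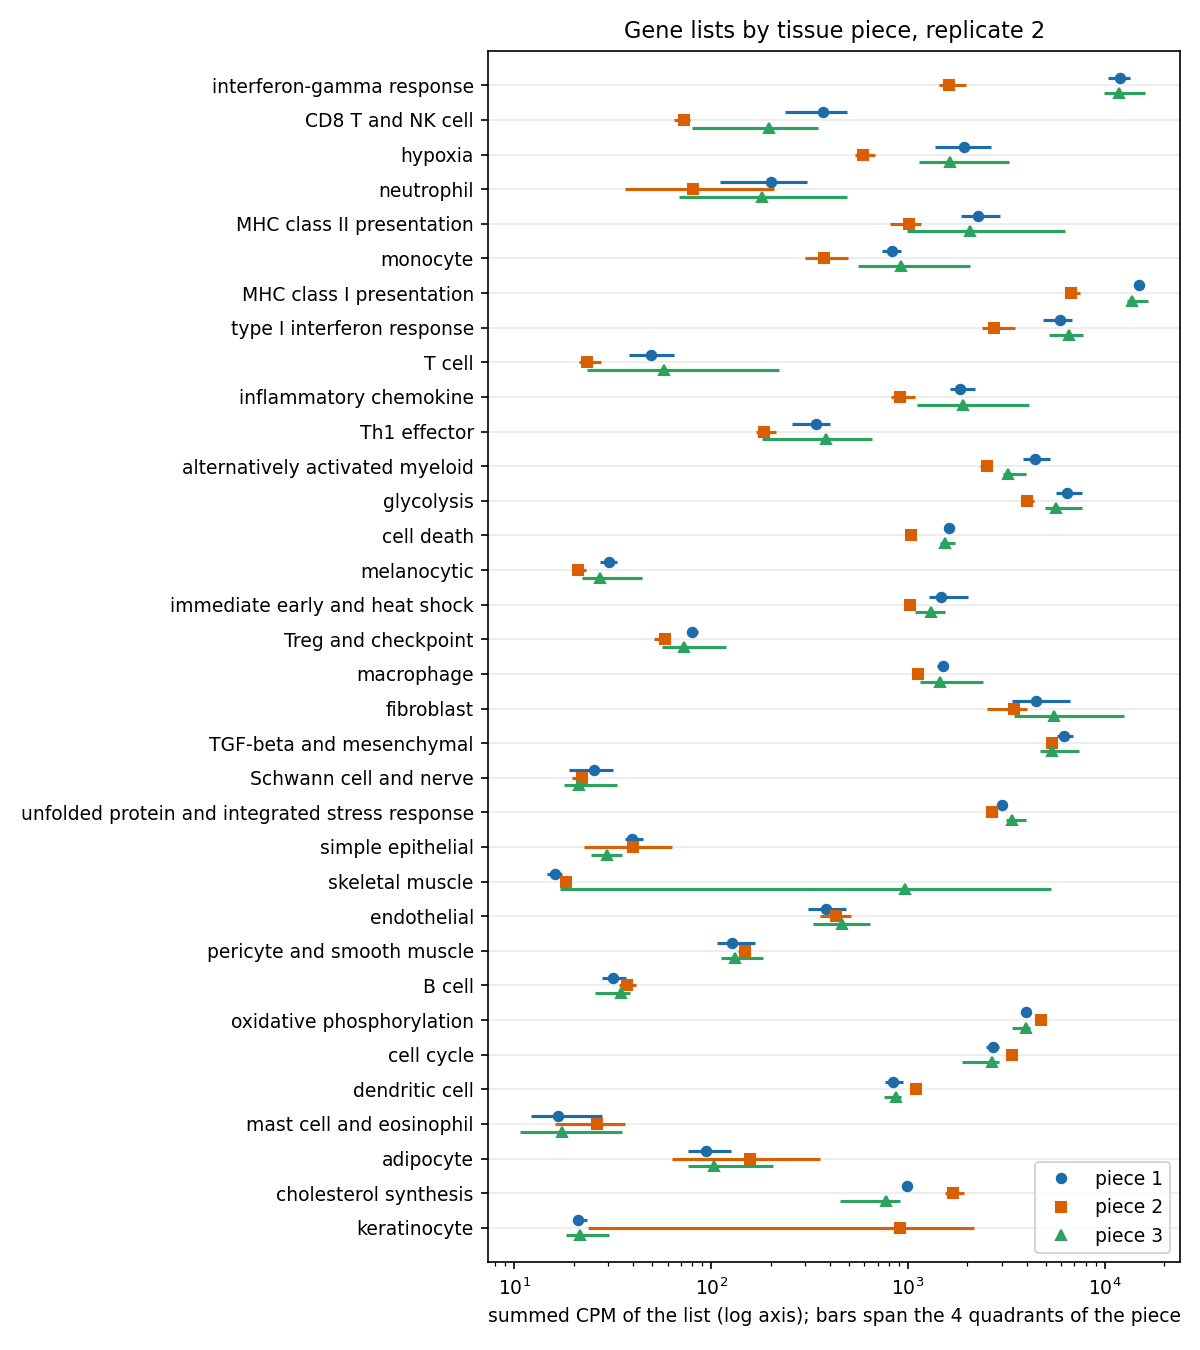
Summed CPM of each of the 34 gene lists (log axis) in pieces 1, 2 and 3 of replicate 2; symbols give the whole piece and bars span its 4 quadrants. The interferon-gamma response list of piece 2 (1620.4 CPM) lay apart from those of pieces 1 and 3 (11927 and 11748 CPM), and the keratinocyte and skeletal muscle lists were carried by parts of 1 piece.

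In every piece the fibroblast, T cell, MHC class II, monocyte, macrophage and inflammatory chemokine lists had a higher CPM at the edge than in the interior. The log2 ratio of edge to interior for the fibroblast list was 2.48, 2.81 and 2.17 in pieces 1, 2 and 3. For the T cell list it was 1.28, 1.79 and 0.97, with 95% intervals of 1.17 to 1.40, 1.65 to 1.94 and 0.84 to 1.10. It was 1.19, 1.79 and 1.05 for MHC class II presentation, 0.25, 0.12 and 0.49 for the CD8 T and NK cell list, and for monocytes 1.39, 1.23 and 1.29, for macrophages 0.70, 0.84 and 0.91 and for inflammatory chemokines 1.28, 0.93 and 1.32. The endothelial list gave -0.10, 1.24 and -0.26. A rise at the edge was not particular to the T cell list among lists at low levels. The Schwann cell and nerve list gave 1.43, 1.52 and 0.72, the melanocytic list 0.82, 1.02 and 0.60 and the keratinocyte list 0.48, 8.45 and 0.61. The B cell list gave -0.058, 0.26 and -0.012, with 0.93 in piece 2 without Pax5, and the simple epithelial list -0.52, 3.21 and -0.19. The type I interferon response list was lower at the edge (-0.77, -0.25 and -0.69), as was the cell cycle list (-0.56, -0.47 and -0.42), whereas the interferon-gamma response list was nearly level (-0.07, 0.10 and 0.03). Leaving out the most abundant gene of a list, an alternative chosen after the data were seen, turned the sign of some edge ratios. The Th1 effector list gave -0.63, -0.29 and -0.70 with Ccl5 and 0.54, 0.95 and 0.76 without it, the dendritic cell list -0.093, -0.081 and -0.063 with Fscn1 and 0.94, 1.64 and 0.44 without it, and the alternatively activated myeloid list 0.028, -0.23 and -0.068 with Spp1 and 1.90, 1.44 and 1.20 without it. Without Spint1 the simple epithelial list went from -0.52 to 0.24 in piece 1 and from -0.19 to 0.37 in piece 3. Without Pax5 the B cell list went from -0.058 to 0.47 in piece 1 and from -0.012 to 0.00088 in piece 3, and without Cdh5 the endothelial list went from -0.098 to 0.11 in piece 1. The sign also turned, from ratios near 0, for the T regulatory and checkpoint list in piece 3 (-0.017 to 0.19) and the cell death list in piece 2 (0.023 to -0.091). The highest mean ratios belonged to Cfd (complement factor D), Serpina3n, the acute-phase gene Saa3, Car12, Hp (haptoglobin), Rarres2, Tnxb, Serpinb2, Tmem45a and Efemp1. Saa3 had 431 and 11.0 CPM at the edge and in the interior of piece 1, 188 and 2.51 CPM in piece 2 and 1008 and 76.4 CPM in piece 3. The lowest belonged to the granzyme gene Gzmf, the transferrin receptor gene Tfrc, Gzmc, Rsad2, Apol8, Usp18, Enpp2, Cmpk2, Cxcl10 and Acy1. Gzmf had 10.5 and 50.1 CPM at the edge and in the interior of piece 1, 3.61 and 16.4 CPM in piece 2 and 6.29 and 32.3 CPM in piece 3. Of 9426 genes compared, 6885 (73.0%) had the same direction in all 3 pieces, 355 were at least 2-fold higher at the edge in every piece and 1, Gzmf, was at least 2-fold lower in every piece. Edge spots were also shallower, with median totals of 30286, 26496 and 16474.5 UMIs against 102940, 120144 and 101180 in the interior. CPM is a share of UMIs, so a higher CPM at the edge does not mean more transcript per spot. In piece 3 the T cell list was highest 4 and 5 steps from outside the tissue (107.8 and 106.3 CPM), beyond the spots counted as edge.

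**Figure D3:**
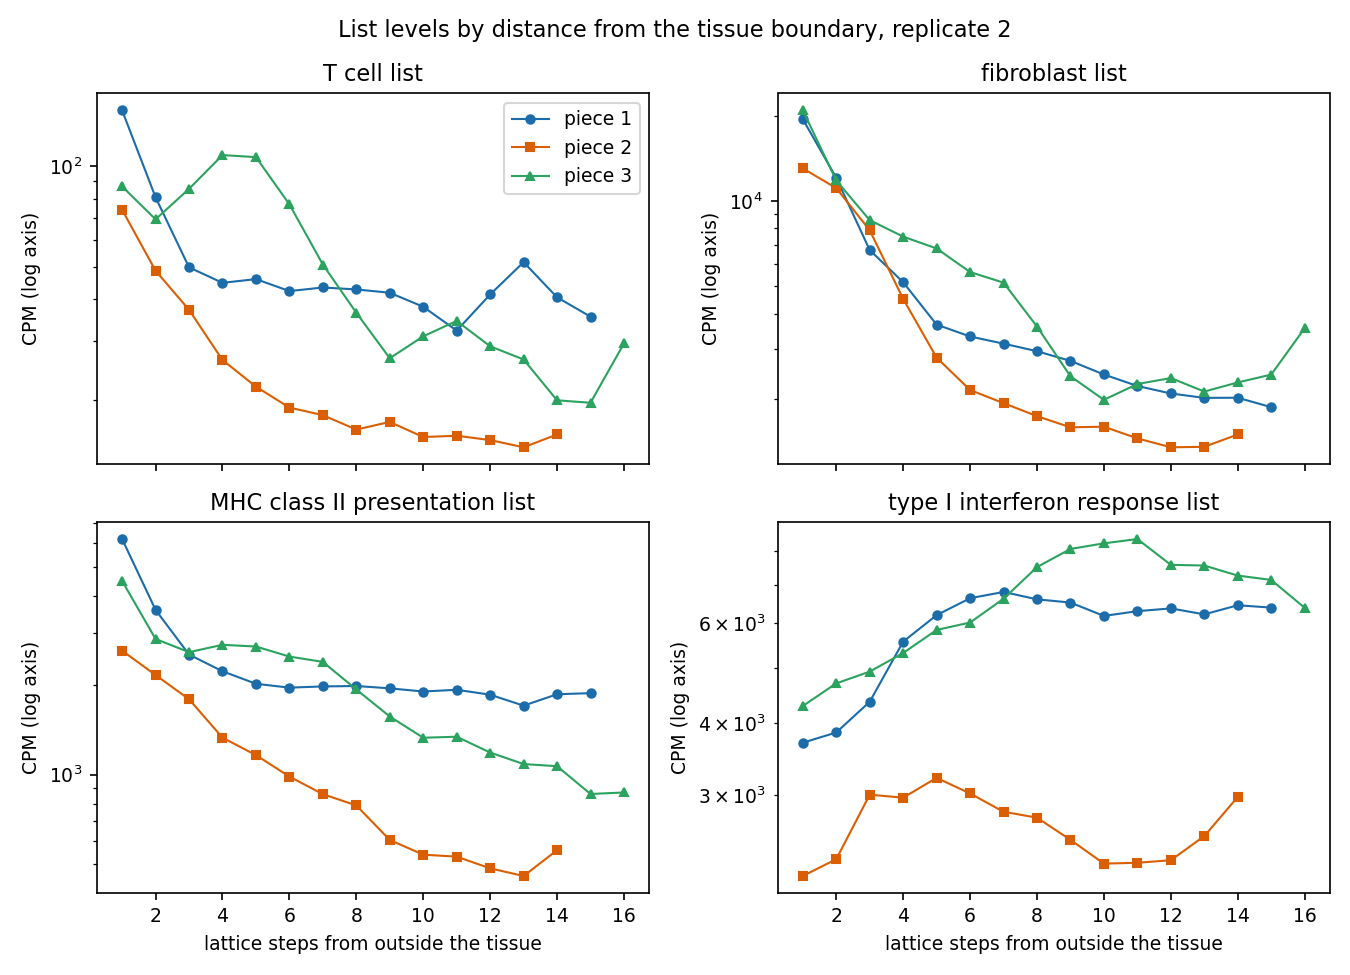
CPM (log axis) of 4 gene lists against lattice steps from outside the tissue, for pieces 1, 2 and 3 of replicate 2, at steps with at least 20 spots. The fibroblast list was higher at the edge than in the interior in all 3 pieces (log2 ratios 2.48, 2.81 and 2.17), and the type I interferon response list was lower (-0.77, -0.25 and -0.69).

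Clustering divided the spots into 10 regions, and pieces 1 and 3 shared 6 of them while piece 2 was almost wholly made of 3 others. Region 5 (765 spots, 70.2% of piece 2) was led by Cx3cr1, Stra6, Myl7, Mest and Fcrls, region 6 (166 spots) by Klk5, Krt14, Lypd3, Col17a1 and Krt6a, and region 9 (156 spots) by Cfd, Cidec, Plin1, Adipoq and Hp, of which Cidec, Plin1 and Adipoq are genes of fat cells. Region 1 was led by Gzmg, Gzmc, Gzmb, Gzmf and Prf1 and held 39.8% of the spots of piece 1 and 10.3% of those of piece 3, with 0% of its spots at the edge. Region 2, with 65.4% of its spots at the edge, was led by the scavenger receptor gene Marco, Prg4, Rbp4, Fcna and Pi16. Region 3 (43 spots in piece 1 and 68 in piece 3) had the T cell receptor genes Trbv13-1, Trbc2 and Trac and the T cell surface gene Cd5 among its leading genes. In region 3 the T cell list reached 652 CPM, 19.2-fold the level of all other spots. MHC class II presentation reached 15510 CPM there (9.98-fold) and the interferon-gamma response list 20678 CPM (2.64-fold). All other spots include piece 2, which held 0 spots of region 3 and had lower levels of these 3 lists. The folds given for regions thus include differences between pieces. Over whole pieces 1 and 3 the interferon-gamma response list was already at 11927 and 11748 CPM. Lists of other cell types were also higher in region 3. The neutrophil list was 8.23-fold, the monocyte list 5.93-fold, the fibroblast list 5.67-fold and the macrophage list 2.90-fold the level elsewhere. The Schwann cell and nerve list differed between pieces there, with 366 CPM in piece 1 and 51.0 CPM in piece 3 against 21.1 CPM elsewhere, while the cell cycle list was at 696 CPM against 2977 CPM elsewhere. Region 4 (9.34% of piece 1 and 29.8% of piece 3) was led by Car6, Avil, Cox6a2, Pla2g2e and Snai2. Region 7 was led by the hypoxia-induced genes Car9 and Egln3 with Aire, G0s2 and Hspa1a, had a hypoxia list level of 4362 CPM (3.92-fold) and a median of only 36503 UMIs per spot. It held 0 spots of piece 2, whose low hypoxia list level (589 CPM) enters the base of this fold. Region 8 was led by Cxcl3, Chga, Mmp8, Cxcl14 and Cxcr2, and region 10 (88 spots, all in piece 3) by Atp2a1, Acta1, Myh4, Casq1 and Mybph. T cell list transcripts were not confined to region 3. In piece 3, thinned spots with at least 3 T cell list UMIs had 19338 CPM of the skeletal muscle list, which holds genes that led region 10. Since piece 2 and the other pieces hardly shared regions, region shares were not compared between them. Regions were clustered on expression, so these genes describe them. All region values come from 1 setting; at the higher resolution there were 17 regions, with an adjusted Rand index of 0.511 to this division.

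**Figure D4:**
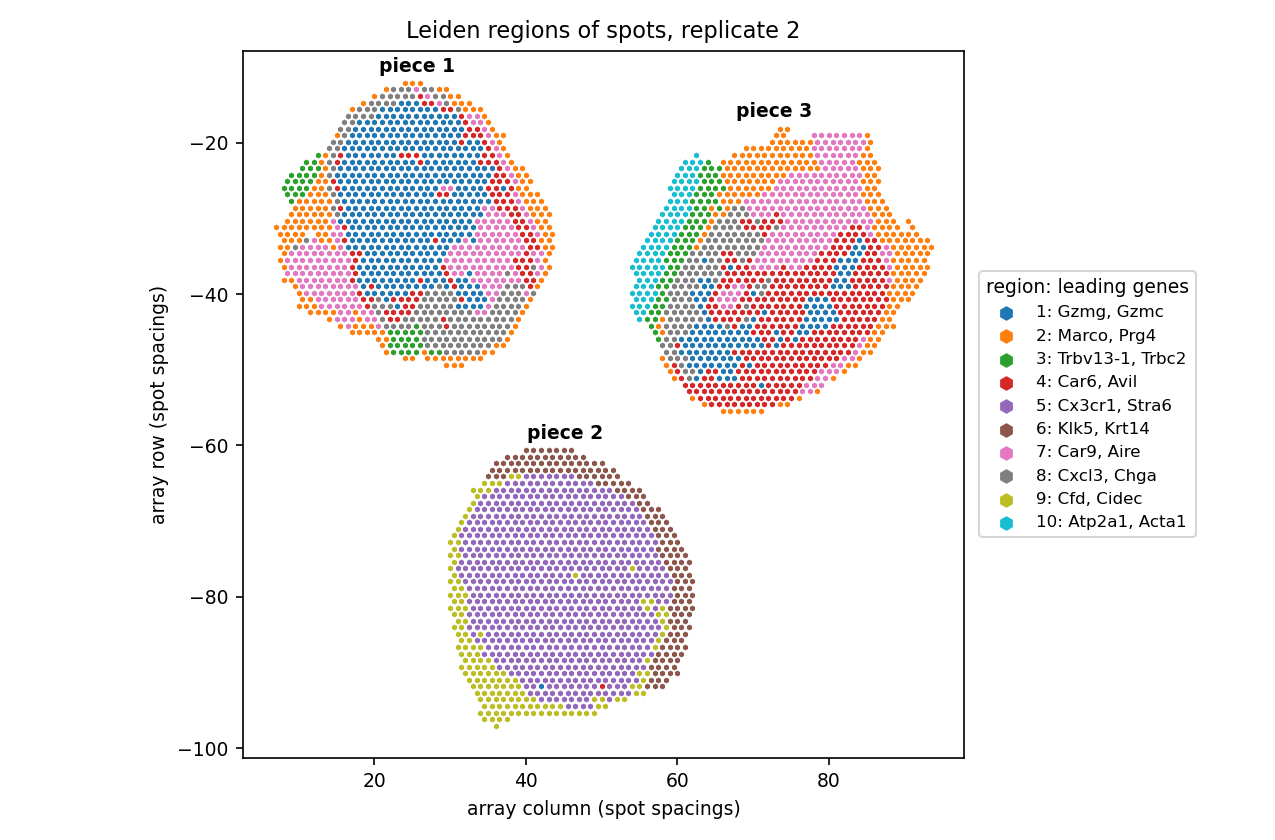
Spots of replicate 2 at their array positions (axes in spot spacings), colored by region, with the 2 leading genes of each of the 10 regions. Regions 5, 6 and 9 lay in piece 2 alone and region 10 (88 spots) in piece 3 alone.

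Among T cell receptor segments, Trbv13-1 (chromosome 6, 41116007 to 41116468), which encodes the variable segment of the beta chain of the Smarta receptor, had 5.17 (95% interval 4.70 to 5.67), 0.930 (0.753 to 1.14) and 12.7 CPM (11.9 to 13.5) in pieces 1, 2 and 3. Region 3 held 32.6% of the Trbv13-1 UMIs of piece 1 and 48.8% of those of piece 3, against 9.63% and 22.9% of those of Trbc1 and 6.63% and 15.4% of those of Trdc. Trbc2 (30.5% and 49.6%), Trac (29.9% and 46.1%) and Traj15 (35.8% and 41.4%) had shares like those of Trbv13-1, and the region was clustered on expression. Of the UMIs of all 19 measured beta-chain variable segments, Trbv13-1 took 29.1% (exact binomial interval 26.8% to 31.4%) in piece 1, 6.83% (5.57% to 8.28%) in piece 2 and 50.5% (48.4% to 52.7%) in piece 3. The variable segments next in UMIs were Trbv29 (1.22, 1.14 and 1.30 CPM in pieces 1, 2 and 3), Trbv1 (1.37, 0.998 and 0.820 CPM) and Trbv30 (0.825, 0.949 and 0.820 CPM). All were above Trbv13-1 in piece 2, so its level there did not stand apart from other segments. The share sets 1 probe signal against other probes and is not read as a share of T cells. These segments were examined after region 3 was seen, and no treatment was assigned to a piece from them.

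Spots with T cell list transcripts had a higher CPM of the MHC class II list in every piece. The planned marking by at least 2 T cell list UMIs took 64.2%, 61.1% and 52.6% of spots in pieces 1, 2 and 3 and followed depth in piece 1, with medians of 96944 UMIs in marked spots and 59622 UMIs at 1 step. Under it the log2 ratio of the interferon-gamma response list in marked to other spots was 0.22, 0.22 and 0.16 in pieces 1, 2 and 3, so piece 2 differed in direction only after thinning. After each spot was thinned to 12490 UMIs, 14.4%, 7.88% and 17.3% of spots were marked, against 5.44%, 8.54% and 5.56% for the B cell list, which other probes read. In thinned spots the interferon-gamma response list was 1.26-fold and 1.76-fold as high in marked as in other spots in pieces 1 and 3 and 0.947-fold in piece 2. With distance from a marked spot (0, 1, 2 and at least 3 steps) it was 14283, 11946, 11169 and 10305 CPM in piece 1. It was 1546, 1680, 1748 and 1541 CPM in piece 2 and 20559, 13054, 11839 and 10902 CPM in piece 3. From spots with 0 to spots with at least 3 T cell list UMIs, MHC class II presentation went from 2033 to 10237 CPM in piece 1, from 1122 to 3048 CPM in piece 2 and from 1854 to 13619 CPM in piece 3. The cell cycle list went from 2619 to 1642, from 3293 to 1875 and from 2475 to 633 CPM. Lists of other tissue moved along the same spots. The fibroblast list went from 5264 to 13902, from 4223 to 15822 and from 8991 to 18335 CPM and the monocyte list from 819 to 2537, from 393 to 605 and from 1065 to 3694 CPM. The skeletal muscle list went from 189.7 to 19338 CPM in piece 3 and the keratinocyte list from 1498 to 16824 CPM in piece 2. The T cell, fibroblast and MHC class II lists were all higher at the edge, so that these relations include position. Thinning left out 109, 35 and 204 spots of pieces 1, 2 and 3.

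**Figure D5:**
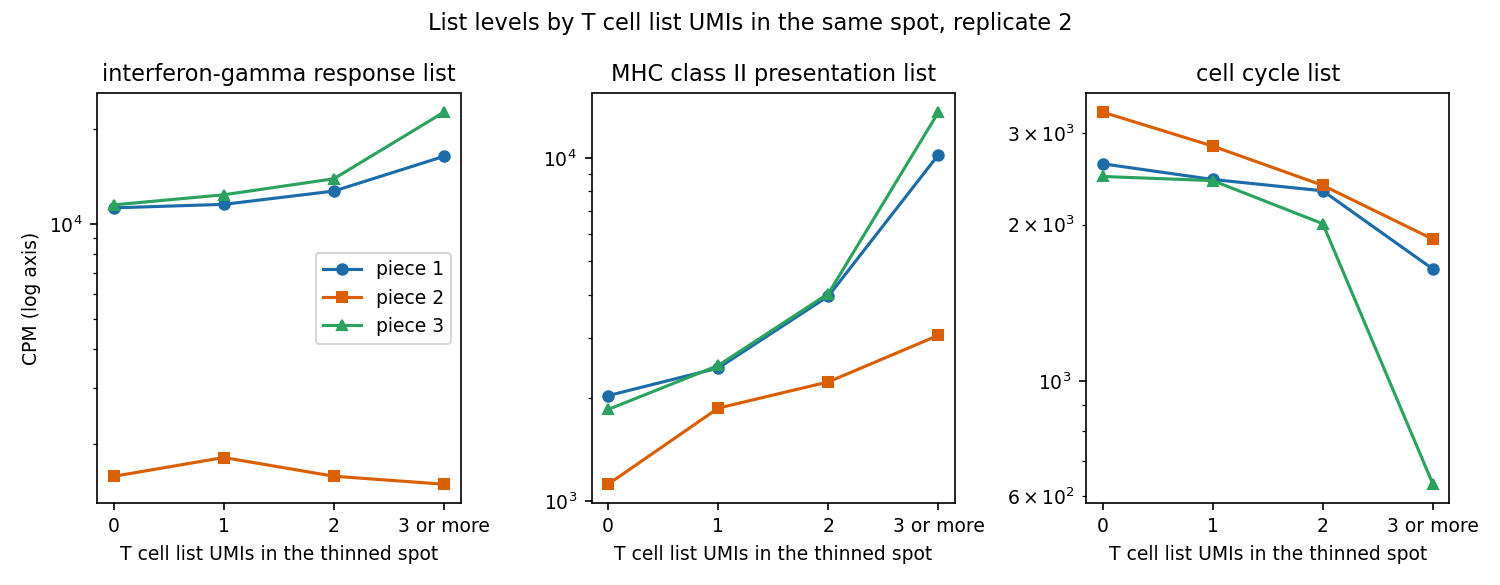
CPM (log axis) of 3 gene lists in spots of replicate 2 thinned to 12490 UMIs, by the number of T cell list UMIs in the same spot, for pieces 1, 2 and 3. The interferon-gamma response list went from 11234 to 16375 CPM in piece 1 and from 11482 to 22631 CPM in piece 3, and was 1577 and 1488 CPM at the ends of piece 2.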

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

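Chosen after the data were seen were the pairs with piece 2, the spots of 50000 to 100000 UMIs, the comparison of marked with all other spots, the edge ratios without the most abundant member, and the choice of the interferon-gamma response and T cell lists to be given in full. Over 102 list ratios and 816 alternatives, 308 stayed within the counting interval, 504 moved beyond it and 4 reversed, counting a change of sign only for ratios of at least 1.5-fold; the interval is narrow at this depth, so a small shift leaves it. Of 296 alternatives of the 37 ratios past 1.5-fold, 281 stayed past 1.5-fold in the same direction and 11 fell below it. The 4 reversals were in interior spots, where piece 2 to piece 1 and to piece 3 gave -0.92 and -1.08 for mast cells and eosinophils and -0.43 and -0.62 for adipocytes. By construction these leave out the fat-bearing border of piece 2.

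The interferon-gamma response list gave log2 ratios of 0.0032 for piece 1 to 3, -2.99 for piece 2 to 1 and -2.98 for piece 2 to 3 in interior spots. In spots of 50000 to 100000 UMIs it gave -0.14 for piece 1 to 3, -2.66 for piece 2 to 1 and -2.80 for piece 2 to 3. With TMM scaling it gave -0.0051 for piece 1 to 3, -2.92 for piece 2 to 1 and -2.94 for piece 2 to 3. With median-ratio scaling it gave -0.0073 for piece 1 to 3, -2.91 for piece 2 to 1 and -2.94 for piece 2 to 3. With each spot weighted equally it gave -0.15 for piece 1 to 3 and -3.02 for piece 2 to 3. Without the most abundant member it gave -0.042 for piece 1 to 3, -2.72 for piece 2 to 1 and -2.77 for piece 2 to 3. The T cell list gave log2 ratios of 0.11 for piece 1 to 3, -1.30 for piece 2 to 1 and -1.20 for piece 2 to 3 in interior spots. In spots of 50000 to 100000 UMIs it gave 0.0070 for piece 1 to 3, -0.60 for piece 2 to 1 and -0.59 for piece 2 to 3. With TMM scaling it gave -1.38 for piece 2 to 3. With median-ratio scaling it gave -1.38 for piece 2 to 3. With each spot weighted equally it gave -0.59 for piece 1 to 3 and -1.62 for piece 2 to 3. Without the most abundant member it gave -0.020 for piece 1 to 3 and -1.01 for piece 2 to 3. The ratios of piece 1 to 3, under 1.5-fold for both lists, thus changed sign under some alternatives, and both T cell ratios of piece 2 shrank at matched depth; the cause was not tested.

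Counts of genes at least 2-fold apart changed by over 1.5 times with the low-value filters and with interior spots. Without the CPM filter and with a minimum of 20 in place of 100 UMIs, changed together, they were 35 higher in piece 1 than 3, 165 lower in piece 1 than 3, 430 higher in piece 2 than 1, 453 higher in piece 2 than 3 and 713 lower in piece 2 than 3. With 50 CPM they were 4 higher in piece 1 than 3, 15 lower in piece 1 than 3, 24 higher in piece 2 than 1, 227 lower in piece 2 than 1, 42 higher in piece 2 than 3 and 232 lower in piece 2 than 3, by construction over fewer genes. In interior spots they were 15 higher in piece 1 than 3, 23 higher in piece 2 than 1 and 56 higher in piece 2 than 3. TMM and median-ratio scaling moved no count by over 1.5 times.

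The T cell list stayed higher at the edge in all 3 pieces under every alternative run. Of 612 alternatives of 102 edge ratios, 269 stayed within the counting interval, 340 moved beyond it and 3 reversed. Of 282 alternatives of the 47 edge ratios past 1.5-fold, 257 stayed past it and 22 fell below it. In the reversals, without Ccl5 the Th1 effector list gave 0.54 in piece 1 and 0.76 in piece 3, by construction without its main gene, and with each spot weighted equally the neutrophil list gave -0.023 in piece 3; the cause was not tested. With an edge of 1 step the T cell log2 ratio was 1.82, 2.14 and 1.18 in pieces 1, 2 and 3. With an edge of 4 steps the T cell log2 ratio was 0.71, 1.30 and 1.21 in pieces 1, 2 and 3. With each spot weighted equally the T cell log2 ratio was 1.83, 2.30 and 1.16 in pieces 1, 2 and 3. With Trbc2 left out the T cell log2 ratio was 1.09, 1.56 and 0.84 in pieces 1, 2 and 3. For the interferon-gamma response list in marked against other spots, the log2 ratios were 0.22, 0.22 and 0.16 as planned. With spots marked by 1 UMI they were 0.18 in piece 1 and 0.14 in piece 3. With spots marked by 3 UMIs they were 0.21 in piece 1, 0.20 in piece 2 and 0.20 in piece 3. With spots thinned to 1 depth they were 0.34 in piece 1, -0.078 in piece 2 and 0.81 in piece 3. Thinning thus turned the sign in piece 2; the cause was not tested. Of 18 alternatives of the 6 ratios of marked to other spots past 1.5-fold, over all lists compared there, 3 fell below it. Resolution 1.0 gave 17 regions, by construction of a finer division. Assignments of spots overlapped in part with those reported, with an adjusted Rand index (1 for equal divisions) of 0.715 at resolution 0.3, 0.511 at 1.0, 0.688 with 1000 and 0.665 with 4000 variable genes. Region contents were not recomputed under these settings. Joining within 4 steps merged 2 pieces of replicate 1. No paired analysis was possible because both libraries belong to 1 group and no test was run.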

Other observations

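Chosen after the data were seen were the pairs with piece 2, on which each test of the interferon-gamma response list rests, the spots of 50000 to 100000 UMIs, the test of single list members and every form of the test of granzyme against receptor transcripts. In interior spots, as over whole pieces, piece 1 had more Gzmc (363 against 124 CPM in piece 3), Prf1 (58.1 against 24.3 CPM), Gzmb, Xcl1, Agt, Igfbp5, Sertad4, Hspa1a and Hspa1b. The 12 lowest ratios there held none of the skeletal muscle genes named for whole pieces. Col1a2 had 117 CPM in the interior of piece 1 and 460 CPM in that of piece 3, the fibulin gene Fbln2 20.2 and 71.0 CPM, the acute-phase gene Saa3 11.0 and 76.4 CPM, and Chga 1.88 and 13.8 CPM. The smooth muscle genes Tagln (3.08 and 12.6 CPM) and Acta2 (7.81 and 24.7 CPM) were also among them. In the same interior spots the fibroblast list differed less than these single genes (2566 and 3290.5 CPM). So did the sum of the pericyte and smooth muscle list, which holds Tagln and Acta2 (114 and 121 CPM). Against piece 3, the interior of piece 2 had more Cx3cr1 (19.6 against 1.64 CPM), Fcrls (11.1 against 1.98 CPM) and Tmem119 (14.4 against 4.18 CPM), genes known from microglia and other resident macrophages, while the macrophage list was lower there (1005 against 1252 CPM). It had less of the macrophage elastase gene Mmp12 (3.99 against 128.6 CPM) and of S100a9 (2.30 against 57.1 CPM).

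The lower interferon-gamma response list in piece 2 was weighed against 3 technical explanations. Dilution by tissue at the edge of piece 2 cannot account for it, since in interior spots the log2 ratios to pieces 1 and 3 were -2.99 and -2.98. Nor can a difference in UMIs per spot, since among spots of 50000 to 100000 UMIs they were -2.66 to piece 1 and -2.80 to piece 3. A few abundant genes do not carry it either, since the median over the 22 members was -3.04 to piece 1 and -3.09 to piece 3, with members between -5.41 and -1.83 and between -5.73 and -1.72. That all 22 members were at least 1.5-fold lower in both pairs was already known, so the median adds no separate support. No biological explanation was tested for this pattern, because the labels give no treatment for a piece.

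T cell list transcripts were weighed against nonspecific probe signal, taking the B cell list as the reference for the spread of such signal. The spread of the T cell list over spots beyond counting error was 10.5, 2.61 and 31.9 times that of the B cell list in pieces 1, 2 and 3, past the bound of 1.5 set in advance. The count expected of each spot was in proportion to its UMIs. Background in proportion to a spot's UMIs thus cannot be the whole source in any piece. Background at an equal level per spot would also be uneven on this scale, because depth differed between spots, and was not excluded. The bound does not tell T cells from other sources. Lists of other cell types passed it too: in piece 1 the Schwann cell and nerve list (20.6 against 1.20 for B cells and 12.7 for T cells), in piece 2 this list, the melanocytic and the simple epithelial list (5.31, 2.37 and 29.9 against 1.27 and 3.32), and in piece 3 the same 3 (3.03, 2.31 and 1.73 against 1.10 and 35.0). Levels of the 2 lists in piece 2 were 58.2 and 42.5 CPM at the edge and 16.8 and 35.6 CPM in the interior for T and B cells. They come from different probes and set no background level for the T cell genes. Whether background spread in another way adds to the signal stays open, and no biological explanation was tested.

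A test of whether cells carry granzyme and perforin transcripts with T cell receptor transcripts in 1 constant ratio took 6 forms, which differed in places, genes or rule and in their outcomes, so no verdict is drawn and the values are given alone. The first form compared regions 1 and 3, which were themselves clustered on expression. There the log2 ratio of receptor to Gzmb, Gzmc and Prf1 transcripts, region 1 against region 3, was -3.16 in piece 1 and -4.92 in piece 3. The later forms compared edge and interior. Receptor constant-chain transcripts (Trac, Trbc1 and Trbc2) were 46.3 CPM at the edge and 15.5 CPM in the interior of piece 1, while Gzmb, Gzmc and Prf1 together were 479 and 622 CPM. The log2 ratio of receptor to these 3 transcripts was 1.96, 3.18 and 1.67 higher at the edge in pieces 1, 2 and 3, for genes picked after their values were seen. With the 4 granzyme and perforin genes of the list fixed beforehand (Gzma, Gzmb, Gzmk and Prf1) it was 1.34 (95% interval 1.17 to 1.52), 2.46 (95% interval 2.17 to 2.76) and 0.69 (95% interval 0.48 to 0.89) higher in pieces 1, 2 and 3, but these intervals cover counting error only and the difference ranged from -0.16 to 2.46 over the quadrants of piece 1, from 1.26 to 5.34 in piece 2 and from -1.47 to 0.68 in piece 3, where the lowest had 1 receptor UMI at the edge. Receptor transcripts in piece 2 were 21.7 CPM at the edge and 4.46 CPM in the interior and those of the 4 genes 41.4 and 46.9 CPM; no value measures the background of these probes.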
